A study of Oryzias latipes with 20 samples.

How the data were processed

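The series holds 20 RNA samples of medaka (Oryzias latipes) brain tissue that combined ventral telencephalon, hypothalamus and pituitary, taken on 7 days after a transition. Per the labels' protocols, DNase-treated total RNA was enriched for polyadenylated RNA and made into strand-specific libraries read from both ends. The authors deposited 1 table of FPKM values per gene and sample, per the file headers. Bowtie2 (2.2.5) and RSEM (1.2.12) are named in the submitters' processing notes, while the genome build and the gene annotation version are not given in the sources used here. FPKM divides the fragments assigned to a gene by its length and the library's total, so a few very abundant genes lower the values of the rest.

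The table had 22615 genes, of which 21722 identifiers matched the RefSeq gene table of assembly ASM223467v1, used for names only, and 893 were the authors' own predicted genes. The symbols of 9 genes had been turned into dates and were restored from that table by identifier. Where 2 entries shared a symbol, the identifier was kept with it. Names in brackets after a locus number come from the protein description in the deposited table. Values had 2 decimals and whole reads could not be recovered, so depth is unknown. The smallest steps between low values, in 4 to 12 genes per library, put the value of 1 fragment at 0.951 to 1.052 times that of the first library. RSEM shares reads between near-identical copies, so values of gene families may be split. The symbol npb has 2 entries, and whether their reads were split was not tested.

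Tests used limma (3.58.1) in R (4.3.3) on log2(FPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 FPKM were tested, 15947 in all, of which 8822 had a symbol, 6601 only a locus number and 524 were predicted genes. 1 linear model with a mean per day gave a moderated F test over all days, one over days 7 to 150, and each day against day 0, two-sided, with a prior variance that follows the mean level. Spread per gene was shared by all 20 samples, with 13 residual degrees of freedom and a median residual SD of 0.16 on the log2 scale. A second model gave the slope per 30 days. P values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 6 day comparisons share the 3 libraries of day 0, so calls of different days were not set against each other. Groups were taken from the labels' days.

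Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of these lists, 33 had at least 3 tested members and were tested with camera (preset correlation 0.01), with camera under an estimated correlation, and with fry, adjusted over the lists within each comparison. The pigment cell list had 2 tested members and was left out. Lists match symbols or their synonyms, so genes under a locus number without such a synonym are missed. Growth hormone, prolactin, somatolactin and thyrotropin beta are not in the pituitary hormone list, while the neuropeptide list does hold LOC101160739. The list of retina genes took in rhob, a GTPase, through the suffix rule. Named genes were, among genes with a symbol, the 6 highest and 6 lowest past the threshold without overlap for each day, the 10 steepest slopes each way past it, the 10 smallest p over days 7 to 150, up to 4 members per list described by F test p, and fixed hormone genes.

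Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, rescaling to the same total, a prior without a trend, sample weights, spread from the compared groups only, trends over days 7 to 150 and on log2(day + 1), the F test without day 60, and each sample left out. Settings added after seeing the data were the removal of day 60 replicate 1 and day 150 replicate 2, that of day 90 replicates 1 and 3, and the same alternatives for the lists. The gene tests were tested on simulated data with the real means and spread, 200 genes being changed. For day 120 they recovered 49.3% of genes changed by 0.5, 80.6% by 1 and 87.9% by 2 on the log2 scale, with 8 false calls. These shares may overstate what the real comparisons can find. The simulated noise was independent between genes, and 200 changed genes make the adjusted threshold easier to pass than a few do. In the real day 120 comparison cga, with a log2 change of 2.94, did not pass. Its spread, shared by all days, includes a wide gap at day 60, with 21.67 FPKM in replicate 1 and 147.91 in replicate 2. Python (3.11.15) with pandas (2.3.3), numpy (2.4.6) and matplotlib (3.10.9) was used for tables and plots. Sex of the fish, hour of sampling and sequencing batch are not given in the sources used here.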

Results

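RNA was sequenced from a block of medaka brain that held the ventral telencephalon, the hypothalamus and the pituitary. The fish were kept under a constant photoperiod and sampled 0, 7, 30, 60, 90, 120 and 150 days after a transition to conditions the labels abbreviate as LW. Each day had 3 samples except day 60, which had 2, giving 20 samples in all. The values are FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) for 22615 genes, and 15947 genes with a mean of at least 1 FPKM were tested. Total FPKM per library lay between 374770 and 405678, the read depth behind it is unknown, and the number of samples sets the precision. The labels name separate samples but not separate fish, so the p-values measure the spread between these samples. Spearman correlations between libraries, across genes, ran from 0.946 to 0.971, with a mean of 0.967 within a day and 0.964 between days.

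The comparison over the 7 days asked which transcripts differed between any sampling days. It includes day 0, the day of the transition, so it can hold effects of the transition as well as later change. The test over days 7 to 150 leaves day 0 out. In limma's F test, 15 genes changed, and 15 changed among days 7 to 150, with 13 genes in both sets. The genes below are a part of them, set out by the day of their highest mean. Transcripts of the gonadotropin lhb, of the neuropeptide gene npb and of a peptide YY-like gene (LOC101160582) had their highest means at day 120. The histone methyltransferase gene dot1l, the histone demethylase gene LOC101164833 (KDM6B), LOC101164758 (AUTS2), the uncharacterized LOC101161642 and the clock repressor gene LOC101174341 (NR1D1) had theirs at day 7. The FKBP5-like gene LOC101157675, kctd3 and phkg2 had theirs at day 90, and the uncharacterized LOC101157693 had its highest mean at day 60. The LOC genes were chosen after their values were seen, because the rule for named genes takes symbols only. With each of the 20 libraries left out in turn, the calls over all days of lhb, LOC101161642, LOC101157675 and LOC101157693 were kept in 20 runs, those of KDM6B and AUTS2 in 19 (lost without day 7 replicate 2) and that of the peptide YY-like gene in 19 (lost without day 0 replicate 1). Those of dot1l, NR1D1 and kctd3 were kept in 18, that of npb in 17 and that of phkg2 in 9 (adjusted p up to 0.118). Without day 7 replicate 2, 7 genes passed the test over all days, while 37 passed without day 60 replicate 2 or without day 90 replicate 2, 24 without day 60 replicate 1 and 25 without day 120 replicate 1. Among days 7 to 150, 9 genes passed without day 7 replicate 2, day 7 replicate 3 or day 30 replicate 1, 27 without day 120 replicate 1, 28 without day 150 replicate 3, 43 without day 90 replicate 2 and 47 without day 60 replicate 2. Without day 90 replicates 1 and 3 together, 12 genes passed in each test, 10 and 9 of them from the sets above, and over all days dot1l, LOC101157675, kctd3 and phkg2 were lost.

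The day 7 comparison asked what differed 7 days after the transition, against the 3 samples of day 0. In limma's test 9 genes rose and 1 fell. The H3K79 methyltransferase gene dot1l rose from 39.2 ± 0.624 to 67.8 ± 7.34 FPKM (mean ± SD, n = 3 each), a log2 change of 0.77 with a standard error of 0.10. The tRNA-modifying enzyme gene trmu rose from 7.443 ± 0.2996 to 11.55 ± 0.9539 FPKM. Among genes with a locus number, NR1D1 (LOC101174341) rose from 5.707 ± 0.5988 to 13.98 ± 2.015 FPKM, KDM6B (LOC101164833) by 0.71, AUTS2 (LOC101164758) by 0.75, the clock activator ARNTL2 (LOC101174183) by 0.76 and MAPKBP1 (LOC105356884) by 0.48 on the log2 scale. The uncharacterized LOC101161642 rose by 0.90, and the Bcl-2 family gene LOC101160592 (BOK) fell by 0.59. LOC110013550 was listed at 0, 0 and 0.04 FPKM at day 0, at 4.32, 6.04 and 4.67 FPKM at day 7 and at 4.64 FPKM in day 60 replicate 2, so no fold is given for it. These genes were at 0.0427 or below in adjusted p, each with values that did not overlap between the 2 days, which chance gives in 10% of genes with 3 values against 3. They were selected by a test on the same values, so the lack of overlap is no separate evidence. The genes with a locus number were chosen after their values were seen. With 1 of the 20 libraries left out, the AUTS2 call was kept in 20 runs, that of NR1D1 in 19 (lost without day 7 replicate 3), of dot1l in 17 (lost without day 0 replicate 2 or 3 or day 7 replicate 3) and of LOC101161642 in 16 (lost without any 1 day 0 library or day 7 replicate 3). Those of trmu and BOK were kept in 13, of LOC110013550 in 12, of KDM6B and MAPKBP1 in 5 and of ARNTL2 in 4 (adjusted p up to 0.256). In 10 other settings, the LOC101161642 call was kept in 10, those of AUTS2, NR1D1 and dot1l in 9, those of trmu and BOK in 7, that of MAPKBP1 in 5 and those of KDM6B and ARNTL2 in 4 (adjusted p up to 0.158), and that of LOC110013550 in 7 of 9. With spread from the compared groups only, 2 genes passed, LOC101161642 and LOC110013550. Without day 90 replicates 1 and 3, 6 passed, 5 of them from the 10.

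Further genes at day 7 missed the threshold over all genes tested. The translation factor gene eif4a2 stood at 55.1 ± 3.67 against 73.6 ± 4.45 FPKM (log2 change −0.41, adjusted p = 0.0583 in limma), and the clock gene per1 at 8.62 ± 1.18 against 13.9 ± 1.19 FPKM (−0.63, adjusted p = 0.212). The Krüppel-like factor gene klf11, which changed over the days in both F tests, was at 1.92 ± 0.515 FPKM at day 7 and 4.237 ± 1.445 at day 0. Its calls were mostly lost with 1 library left out, being kept in 5 of 20 runs over all days (adjusted p up to 0.125) and in 9 over days 7 to 150 (up to 0.106), and over all days in 3 of 9 other settings. In the list of glucocorticoid response genes, 3 of 15 members had a positive change, none passed over all genes and 2 were lower when adjusted over the list alone (per1 and zbtb16). Its camera call towards lower values (adjusted p = 0.00299) was lost, with adjusted p = 0.398 with an estimated correlation. The 30 heat shock and chaperone genes also ranked lower (camera adjusted p = 0.00299, and adjusted p = 0.773 with an estimated correlation). The 15 hypothalamus markers ranked higher, with a median of 0.16 (camera adjusted p = 0.00113, and adjusted p = 0.511 with an estimated correlation). The 66 ribosomal protein genes ranked lower, with a median of −0.11 (camera adjusted p = 6.11e-07, and adjusted p = 0.805 with an estimated correlation). Their median was 0.017 once the libraries were quantile normalized, −0.07 after rescaling to the same total and −0.17 without day 0 replicate 3. The heat shock call was lost without day 7 replicate 2 (median −0.04, from −0.09), and its median was −0.04 without day 0 replicate 3 and −0.045 after rescaling. The glucocorticoid call was lost without day 7 replicate 1 (−0.13, from −0.15), and the hypothalamus median was 0.10 without day 0 replicate 1. Without 1 of the day 0 libraries, 4, 2 or 2 genes passed the gene test (replicates 1, 2 and 3), and without 1 of the day 7 libraries, 5, 6 or 1 did. It called 4 genes without day 90 replicate 2 and 5 without day 150 replicate 2.

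**Figure D1:**
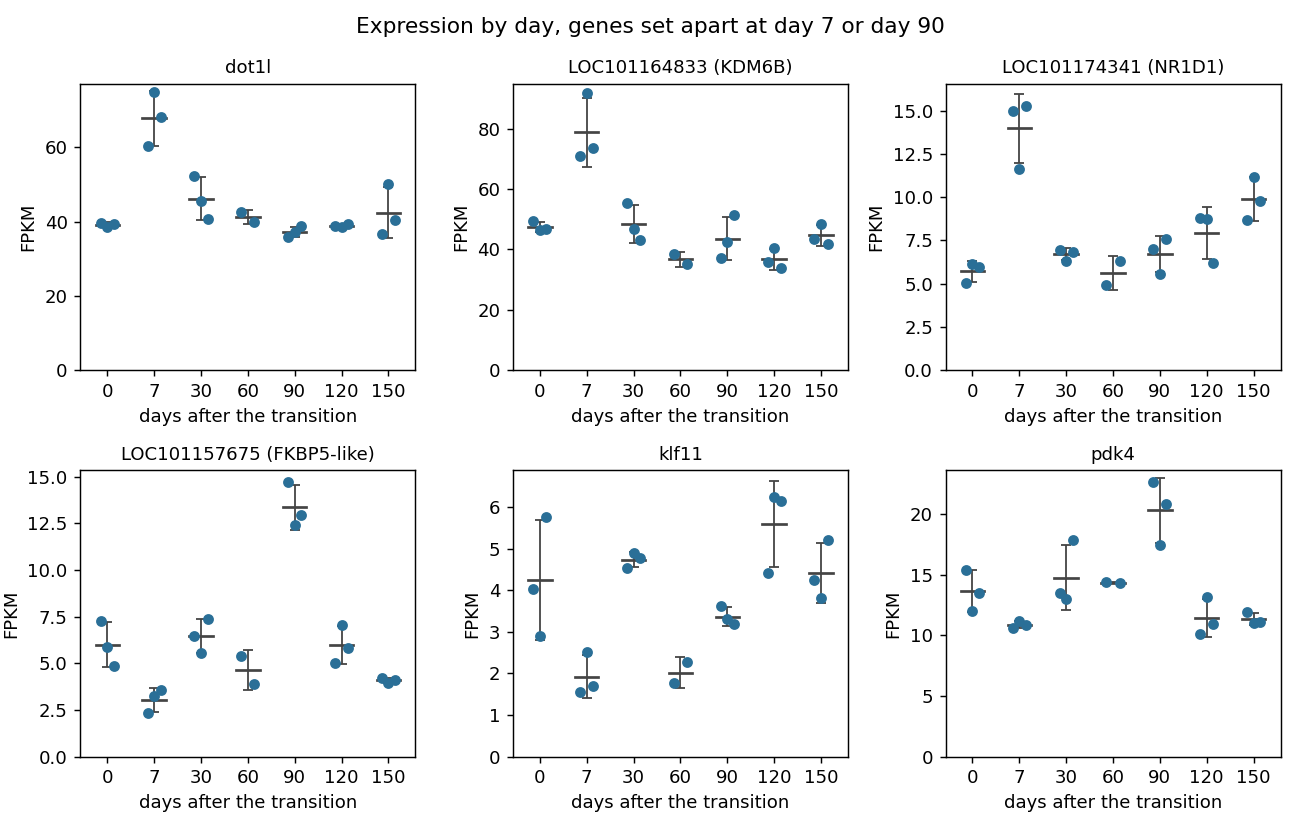
FPKM by day for 6 genes; each point is a library, the horizontal line the mean and the bar 1 SD, with 3 libraries per day and 2 at day 60. The 3 day 7 libraries of dot1l lie at 60.3, 74.9 and 68.2 FPKM, and the FKBP5-like gene reaches 13.4 FPKM on average at day 90.

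The day 120 comparison asked what differed 120 days after the transition. The luteinizing hormone subunit gene lhb rose from 27.0 ± 9.58 to 214 ± 39.0 FPKM, a log2 change of 2.97 with a standard error of 0.42 (limma adjusted p = 0.0167, n = 3 each). Neuropeptide B (npb, identifier 105354556) rose from 61.9 ± 18.0 to 311 ± 32.1 FPKM, a log2 change of 2.35. The peptide YY-like gene LOC101160582 rose from 6.17 ± 0.145 to 70.7 ± 25.9 FPKM, a log2 change of 3.26. The planar polarity gene LOC101170632 (VANGL1) rose by 1.01, and calcrl, a receptor of calcitonin gene-related peptide and adrenomedullin, fell by 0.43 on the log2 scale. LOC101160582 and LOC101170632 were chosen after their values were seen. In total 4 genes rose and 1 fell. Rescaling to the same total or quantile normalization gave 3 higher and 0 lower. Without any 1 of the 3 day 0 libraries, or without day 120 replicate 1 or 2, 0 genes passed the gene test at day 120, and 1 passed without day 120 replicate 3. Without day 7 replicate 1 or 2, any 1 of the day 30 libraries, or day 90 replicate 2, 3 passed. The count was 8 without day 150 replicate 1 or 2, 9 without day 90 replicate 3, and 11 and 10 without day 60 replicates 1 and 2. Without day 60 replicate 1 and day 150 replicate 2 together, 13 passed. The calls of lhb, npb and the peptide YY-like gene were kept in 14 of 20 runs with 1 library left out and lost in the 6 without a library of day 0 or day 120 (adjusted p up to 0.160, 0.124 and 0.124). Those of calcrl and VANGL1 were kept in 6 of 20 (up to 0.229 and 0.223) and lost after quantile normalization or rescaling.

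Other genes of the reproductive axis lay higher at day 120 without passing the threshold over all genes. The shared glycoprotein hormone subunit gene cga was at 595.5 ± 84.1 against 78.6 ± 25.1 FPKM (log2 change 2.94, limma adjusted p = 0.0959), and fshb at 242 ± 71.7 against 58.4 ± 18.1 (2.04, adjusted p = 0.333). The spread behind both p values is shared by all days and includes the gap between the day 60 libraries. Replicates 1 and 2 of day 60 were at 21.67 and 147.91 FPKM for cga and 18.46 and 162.24 for fshb. Brain aromatase, cyp19b, which makes oestrogens from androgens, was at 378.5 ± 104 against 94.7 ± 17.9 FPKM (1.97, adjusted p = 0.0850). The progesterone receptor gene pgr was at 3.25 ± 0.426 against 0.923 ± 0.252 FPKM (1.15, adjusted p = 0.0539). In the 4-gene list of pituitary hormones (lhb, cga, fshb and pomc), 1 gene rose over all genes, 3 rose when adjusted over the list alone, and pomc did not (0.21). That list ranked higher at day 120 (camera adjusted p = 1.37e-05, and adjusted p = 0.139 with an estimated correlation). The 14 sex steroid genes ranked higher too (camera adjusted p = 0.00155, and adjusted p = 0.139 with an estimated correlation), with npb higher over all genes and 4 (npb, cyp19b, pgr and esr1) adjusted over the list alone. Of 25 neuropeptide genes, npb rose and 5 were higher when adjusted over the list alone. Among them were vip at 35.9 ± 3.48 against 24.0 ± 5.15 FPKM, and the gene with the symbol oxt, whose protein is described as vasotocin-neurophysin, at 116 ± 5.61 against 71.9 ± 18.6. The neuropeptide list had camera adjusted p = 0.000429, and adjusted p = 0.126 with an estimated correlation. The pituitary cell regulators, 13 genes such as pitx1 and scg2, had a median of 0.28 and 12 positive (camera adjusted p = 0.00207, and adjusted p = 0.0883 with an estimated correlation), and of 0.16 without day 120 replicate 1. The neuropeptide median of 0.21 was 0.34 without day 0 replicate 3. The sex steroid median of 0.17 was 0.11 without day 0 replicate 1 or without the filter, and 0.06, with the call lost, at a mean of at least 5 FPKM.

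Chaperones and enzymes of the endoplasmic reticulum ranked higher at day 120 as a list (camera adjusted p = 2.67e-09, and adjusted p = 0.0815 with an estimated correlation), though not as single genes over all genes tested. In the list of the unfolded protein response, 20 of 22 genes had a positive change with a median of 0.28, none passed over all genes, and 11 were higher when adjusted over the list alone. The disulfide isomerase gene pdia4 stood at 21.78 ± 2.201 against 14.74 ± 1.204 FPKM (log2 change 0.53), pdia6 at 0.45, chac1 at 0.45 and the stress sensor gene atf6 at 0.31. The list had fry adjusted p = 0.00901. The 48 oxidative phosphorylation genes had a median of 0.18, with 46 positive and 10 higher when adjusted over the list alone (camera adjusted p = 8.50e-13, and adjusted p = 0.199 with an estimated correlation), and the median was 0.28 without day 120 replicate 1 and 0.11 after quantile normalization. The 66 ribosomal protein genes had a median of −0.16, with 3 positive (camera adjusted p = 1.51e-15, and adjusted p = 0.341 with an estimated correlation), or −0.10 without day 0 replicate 1. Hypothalamus markers had a median of 0.17, with all 15 positive (adjusted p = 0.142 with an estimated correlation), and the 7 microglia and leukocyte genes one of −0.43, with 0 positive (adjusted p = 0.341 with an estimated correlation). Heat shock genes (median 0.13) and cholesterol synthesis genes (0.19) also ranked higher, with adjusted p = 0.456 and adjusted p = 0.601 with an estimated correlation. The calls of both were lost in several settings, that of the heat shock genes without day 0 replicate 2 (median 0.06) or day 120 replicate 3 (0.03), with a median of 0.07 after quantile normalization, and that of the cholesterol genes without day 0 replicate 1 (0.14) or 2 (0.165), without day 120 replicate 3 (0.19), or at a mean of at least 5 FPKM (0.09). The leukocyte call was lost without day 0 replicate 2 (−0.27), day 120 replicate 3 (−0.26) or the filter (−0.13), and its median was −0.23 without day 120 replicate 2.

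**Figure D2:**
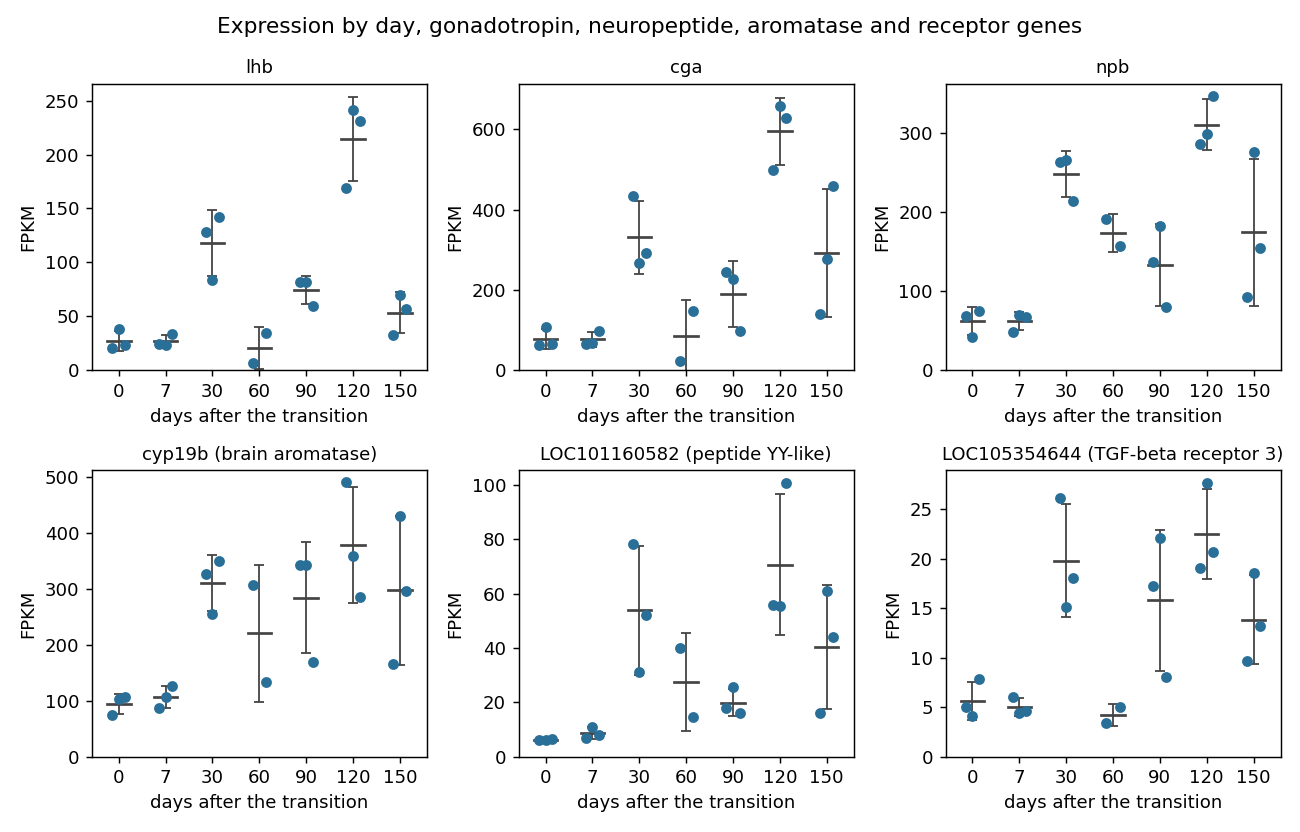
FPKM by day for 6 genes; each point is a library, the horizontal line the mean and the bar 1 SD, with 3 libraries per day and 2 at day 60. The day 120 libraries of lhb lie between 169 and 241.5 FPKM and those of day 0 between 20.2 and 38.0 FPKM.

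At day 30 the question was the same, 30 days after the transition, and 0 genes passed limma's test, with 1377 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0666. Several genes of the day 120 account had high means here. The peptide YY-like gene LOC101160582 was at 53.8 ± 23.6 against 6.17 ± 0.145 FPKM (log2 change 2.84, adjusted p = 0.0666), npb at 248 ± 29.2 FPKM (2.02, adjusted p = 0.0779), lhb at 118 ± 30.4 FPKM (adjusted p = 0.148) and cyp19b at 310.0 ± 49.9 FPKM (1.71, adjusted p = 0.161). The immediate early genes egr1 and npas4 were at 39.7 ± 4.83 and 12.8 ± 1.66 FPKM, against 27.2 ± 4.51 and 8.82 ± 1.14 at day 0. Pituitary hormones had a median of 1.83 with 3 of 4 higher adjusted over the list alone (camera adjusted p = 0.000623, and adjusted p = 0.239 with an estimated correlation). For the unfolded protein response list the median was 0.24 with 4 of 22 higher adjusted over the list alone (camera adjusted p = 2.31e-05, and adjusted p = 0.150 with an estimated correlation). Hypothalamus markers also ranked higher, with a median of 0.26 (adjusted p = 0.150 with an estimated correlation), as did the pituitary cell regulators, with a median of 0.23 (adjusted p = 0.126 with an estimated correlation). The sex steroid genes (median 0.11, 12 of 14 positive) and the neuropeptide genes (0.08, 19 of 25 positive) were also called higher (adjusted p = 0.239 each with an estimated correlation). The sex steroid call was lost without day 30 replicate 2 (0.12) or at a mean of at least 5 FPKM (0.01), its median was 0.07 without the filter, and it was 0.22, 0.18 and 0.17 without day 0 replicate 3 and day 30 replicates 1 and 3. The neuropeptide call was lost without day 0 replicate 2 (0.08) or day 30 replicate 3 (0.14), and its median was 0.19 without day 0 replicate 1 and 0.145 without day 30 replicate 1. The ribosomal protein genes ranked lower (median −0.05, 11 of 66 positive, adjusted p = 0.820 with an estimated correlation), a call lost without day 0 replicate 1 (−0.01) or 2 (−0.03), day 30 replicate 1 (−0.025) or after quantile normalization (−0.02), with a median of −0.12 without day 0 replicate 3. A pseudocount of 0.1 gave 3 genes, sample weights 5, spread from the compared groups only 2, and leaving out day 60 replicate 1 and day 150 replicate 2 together 5. Leaving out day 60 replicate 1 or 2 gave 2 genes, and day 150 replicate 1 or 2 gave 4.

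The day 60 comparison had 2 samples against 3, and 1 gene rose, with 1105 at an unadjusted p under 0.05. The uncharacterized LOC101157693, chosen after its values were seen, rose from 5.06 ± 0.363 (n = 3) to 20.65 and 18.55 FPKM, a log2 change of 1.77 with a standard error of 0.13 (limma adjusted p = 8.07e-06). Its means on the other days lay between 5.06 and 6.96 FPKM. The adhesion molecule gene LOC105355183 (CADM4-like) changed over days 7 to 150 and stood at 8.43 and 5.45 FPKM at day 60, against 2.30 ± 0.202 at day 0; it too was chosen after its values were seen. The LOC101157693 call was kept in 20 of 20 runs with 1 library left out, and that of LOC105355183 in 9 (adjusted p up to 0.158) and in 4 of 8 other settings. One of the 2 day 60 libraries, replicate 1, was low in pituitary transcripts: prolactin (LOC101172582) was at 4.79 FPKM there and at 1910 in replicate 2, pomc at 88.6 and 760, the thyrotropin beta subunit (LOC101171658) at 0.740 and 19.2, and pitx1 at 0.150 and 3.58. Its lhb was at 6.61 FPKM, against 34.2 in replicate 2. Among the lists, the ribosomal protein genes (median −0.10) and the leukocyte genes (−0.28) ranked lower and the neuropeptide (0.27) and oxidative phosphorylation genes (0.09) higher, with adjusted p = 0.727, adjusted p = 0.727, adjusted p = 0.668 and adjusted p = 0.727 with an estimated correlation. The neuropeptide call was lost without day 60 replicate 1 (0.24), and the oxidative phosphorylation call without day 0 replicate 3 (0.06), day 60 replicate 2 (0.095) or after quantile normalization (0.04). The leukocyte call was lost without day 0 replicate 2 (−0.25), without day 60 replicate 1 (−0.20), without a filter or at a mean of at least 5 FPKM (−0.22 each). Its median was −0.45 without day 60 replicate 2 and −0.44 with a pseudocount of 0.1. The ribosomal median was −0.06 without day 0 replicate 1 or after quantile normalization, and −0.16 without day 0 replicate 3. Without replicate 1, 8 genes passed the gene test, without replicate 2, 26, without day 120 replicate 1, 2, and without day 60 replicate 1 and day 150 replicate 2 together 7.

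**Figure D3:**
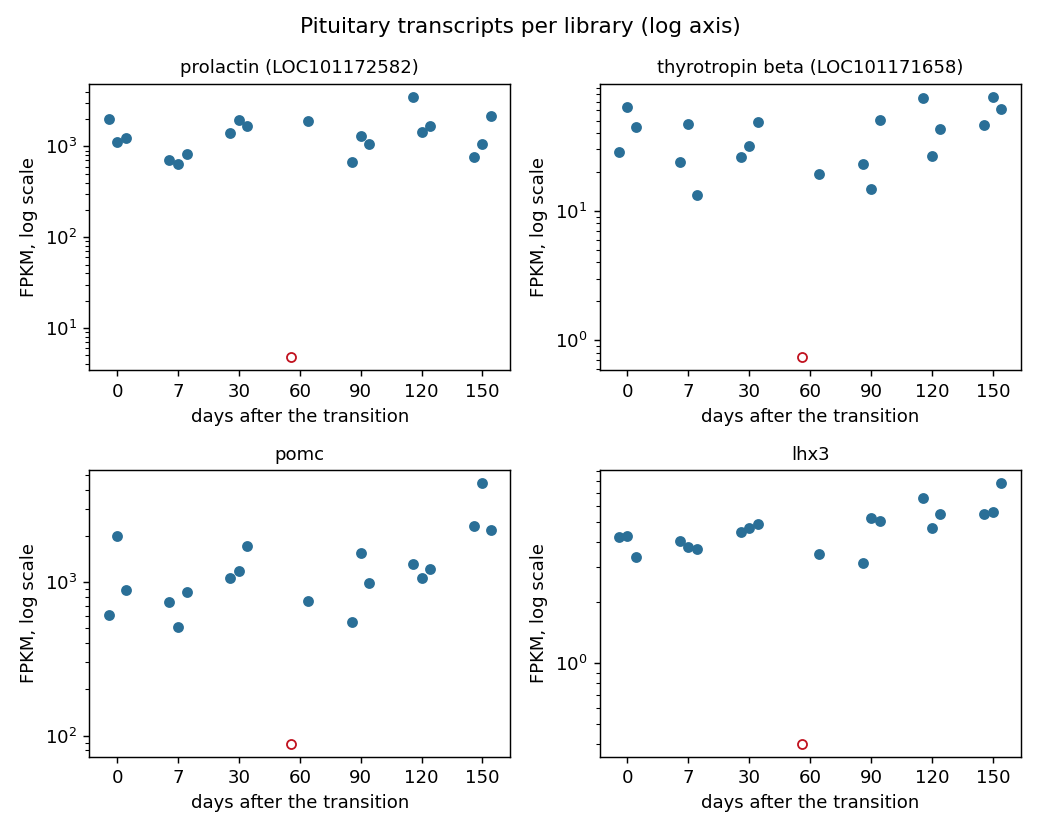
FPKM on a log axis by day for prolactin, thyrotropin beta, pomc and lhx3; each point is a library and the open red circle is day 60 replicate 1. Prolactin is at 4.79 FPKM in that library and between 641 and 3512 FPKM in the other 19.

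At day 90 no gene passed against day 0 in limma's test (0 of 15947, 1319 at an unadjusted p under 0.05, smallest adjusted p 0.0648), while several genes with their highest mean on this day changed in the F tests. The FKBP5-like gene LOC101157675, whose mammalian counterpart is induced by glucocorticoids, ran from 3.05 ± 0.644 FPKM at day 7 to 13.38 ± 1.201 at day 90 (n = 3 each, F test adjusted p = 0.00101). The kinase gene pdk4, which restrains pyruvate oxidation, was at 20.3 ± 2.65 FPKM at day 90 and 13.6 ± 1.71 at day 0 (adjusted p = 0.0297 over days 7 to 150). The phosphorylase kinase gene phkg2 was at 14.8 ± 0.896 against 6.95 ± 1.32 FPKM, and kctd3 at 13.3 ± 0.827 against 9.43 ± 0.427 (F test adjusted p = 0.0346 and 0.0131 over all days). With 1 library left out, the call of LOC101157675 was kept in 20 of 20 runs, that of kctd3 in 18 (lost without day 90 replicate 2 or 3), that of pdk4 in 11 (adjusted p up to 0.137) and that of phkg2 in 9 (up to 0.118). Of these genes, the glucocorticoid response list holds pdk4 but not the FKBP5-like gene, phkg2 or kctd3. Its other members did not pass over all genes, with klf9 at 5.86 ± 1.24 against 2.81 ± 0.605 FPKM and cebpd at 13.95 ± 2.955 against 7.997 ± 0.9943. That list was not called at day 90 (camera adjusted p = 0.111), and had 4 members changed over all days when adjusted over the list alone (pdk4, cebpd, per1 and klf9). The unfolded protein response list had a median of 0.24 with 21 of 22 positive (camera adjusted p = 8.46e-06, and adjusted p = 0.311 with an estimated correlation). Interferon and antigen presentation genes (median 0.40) and insulin axis genes (0.20) ranked higher, with adjusted p = 0.535 and adjusted p = 0.346 with an estimated correlation. The 3 libraries differed in sign for the interferon list, with mean scores of 0.96, −0.22 and 0.30. Its call was lost without day 90 replicate 1 (median 0.10), day 0 replicate 1 (0.29) or at a mean of at least 5 FPKM (0.23), and its median was 0.725 without day 90 replicate 2. The insulin axis call was lost without day 0 replicate 1 (0.19), day 90 replicate 3 (0.16), the filter (0.14) or at a mean of at least 5 FPKM (0.18). The ribosomal list had a median of −0.04 (adjusted p = 0.935 with an estimated correlation), with the sign turned after quantile normalization (0.002) or without day 90 replicate 1 (0.001). Its call was also lost without day 0 replicate 1 (−0.01) or 2 (−0.03), and its median was −0.11 without day 0 replicate 3 and −0.07 without day 90 replicate 3. Without day 90 replicate 2, 60 genes passed at day 90, of which 53 were higher. Without day 0 replicate 1 or 3, day 7 replicate 1, day 90 replicate 3 or day 150 replicate 1, 1 gene passed, and without day 7 replicate 3, 2 did. A mean of at least 5 FPKM gave 1 gene and sample weights 2.

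Replicates 1 and 3 of day 90 lay at −21.1 and −17.0 on the first principal component, with replicate 2 at −7.74, and their mean correlations with the other libraries, 0.961 and 0.962, were the lowest after that of day 150 replicate 2. Mean scores of the insulin axis genes in replicates 1, 2 and 3 were 0.26, 0.08 and 0.35, those of the glucocorticoid response genes 0.21, 0.09 and 0.21, and those of the leukocyte markers 0.40, 0.05 and 0.48. The cytokine signaling gene socs3 (identifier 101170518) was at 15.17, 3.35 and 11.91 FPKM. Without replicates 1 and 3, a setting chosen after seeing the data that leaves 1 library at day 90, the interferon list turned to a median of −0.06, and the insulin axis and ribosomal medians were 0.07 and −0.02, with the 3 calls lost. The F test calls of kctd3, phkg2 and pdk4 were lost as well, and that of LOC101157675 over all days but not over days 7 to 150. In replicates 1, 2 and 3 kctd3 was at 12.33, 13.72 and 13.8 FPKM, phkg2 at 15.79, 14.52 and 14.06 and pdk4 at 22.64, 17.42 and 20.83. That setting keeps 1 library at day 90, so the lost calls do not tell whether replicates 1 and 3 carry these genes. Against day 0, 5 genes passed, 4 of them higher.

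The day 150 comparison also gave 0 genes in limma's test, with 1532 at an unadjusted p under 0.05 and a smallest adjusted p of 0.158. Here pomc, the precursor of corticotropin and melanotropin, had its highest mean, at 2977 ± 1251 FPKM against 1168 ± 732 at day 0 (adjusted p = 0.467). The neuropeptide gene grp was at 4.02 ± 0.328 against 2.28 ± 0.465 FPKM, and gnrh1 at 14.6 ± 1.23 against 6.24 ± 2.24. Of 25 neuropeptide genes, 7 were higher when adjusted over the list alone (camera adjusted p = 0.00206, and adjusted p = 0.232 with an estimated correlation). Oligodendrocyte and myelin genes ranked lower with a median of −0.20 (camera adjusted p = 0.000609, and adjusted p = 0.246 with an estimated correlation), with mpz at 196 ± 73.7 against 340 ± 60.5 FPKM. Replicate 2 carried much of this, with a mean score of −0.48 against −0.05 and −0.07 in replicates 1 and 3 and mpz at 112 against 249 and 228 FPKM. Without it the call was lost and the median was −0.06, while it was −0.32 without replicate 1 and −0.33 without replicate 3, and −0.105 with sample weights. Leukocyte genes had a median of −0.44 (camera adjusted p = 0.000922, and adjusted p = 0.232 with an estimated correlation), a call lost without the filter (−0.29). Replicate 2 of this day lay apart from the other libraries on the first principal component, at 37.1, which carried 9.07% of the variance, and had the lowest mean correlation with the others, 0.954. Leaving it out left the count of genes at 0, and leaving out day 0 replicate 1, day 60 replicate 1 or 2, or day 150 replicate 1 gave 1 gene.

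Further lists were called at day 150. The 15 hypothalamus markers had a median of 0.21 with 14 positive (camera adjusted p = 0.000509, and adjusted p = 0.232 with an estimated correlation). Pituitary hormones (median 1.31) and pituitary cell regulators (0.23, or 0.15 without day 150 replicate 2) ranked higher, with adjusted p = 0.269 and adjusted p = 0.232 with an estimated correlation. The sex steroid genes (0.23) did too (adjusted p = 0.232 with an estimated correlation), a call lost without day 0 replicate 2 (0.23) or at a mean of at least 5 FPKM (0.205). Telencephalon markers (0.255, adjusted p = 0.409 with an estimated correlation) lost their call without day 0 replicate 1 (0.16) or 2 (0.24) or day 150 replicate 1 (0.17) or 3 (0.165). Genes of the unfolded protein response (0.13, adjusted p = 0.345 with an estimated correlation) lost it without day 0 replicate 2 (0.11), day 150 replicate 3 (0.13) or after quantile normalization (0.09). Oxidative phosphorylation genes (0.06, adjusted p = 0.828 with an estimated correlation) kept their call in 3 of 9 other settings and in 16 of 20 runs with 1 library left out. It was lost without day 0 replicate 2 (0.06) or 3 (0.03), day 120 replicate 2 (0.06) or day 150 replicate 2 (0.02), and the median was 0.09 without day 0 replicate 1 and 0.105 without day 150 replicate 3. Extracellular matrix and meninges genes ranked lower (−0.16, adjusted p = 0.232 with an estimated correlation), a call lost without day 0 replicate 2 (−0.065) or day 150 replicate 2 (−0.01), with a median of −0.10 without the filter or with sample weights.

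The linear trend asked which transcripts moved steadily over the 150 days. The delta-sarcoglycan gene sgcd, part of a membrane complex that links the cytoskeleton to the matrix, fell by 0.13 on the log2 scale per 30 days, from 15.1 ± 1.11 FPKM at day 0 to 9.907 ± 2.204 at day 150 (n = 20 samples, limma adjusted p = 0.0284). It was the 1 gene that passed, with 1786 at an unadjusted p under 0.05. Its call was kept in 10 of 20 runs with 1 library left out (adjusted p up to 0.089). The 48 oxidative phosphorylation genes had a median slope of 0.03 per 30 days with 45 positive (camera adjusted p = 4.14e-08, and adjusted p = 0.527 with an estimated correlation; a slope of 0.01 after quantile normalization and 0.02 after rescaling), and 20 of 22 genes of the unfolded protein response had a positive slope (camera adjusted p = 0.000111, and adjusted p = 0.436 with an estimated correlation). A trend over days 7 to 150 or on log2(day + 1), or without day 90 replicates 1 and 3, gave 0 genes. Leaving out 1 library took the count to 0 for day 0 replicate 2, any 1 of the libraries of days 7 and 30, day 90 replicate 2, day 120 replicate 1 and day 150 replicate 2. It took it to 2 without day 0 replicate 1, day 60 replicate 2 or day 120 replicate 3, and to 7 without day 150 replicate 3.

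Further lists were called for the trend. Pituitary hormones (median slope 0.28 per 30 days), neuropeptides (0.03), sex steroid genes (0.04) and heat shock genes (0.02) ranked higher, with adjusted p = 0.527, adjusted p = 0.436, adjusted p = 0.436 and adjusted p = 0.531 with an estimated correlation. The calls of the pituitary hormones and sex steroid genes were lost without the filter (0.24 and 0.03). The heat shock call was lost without day 7 replicate 2 (0.017), without day 120 replicate 3 (0.01) or after quantile normalization (0.006), and its slope was 0.01 after rescaling. Myelin (−0.018), neuron and synapse (−0.011), leukocyte (−0.042) and extracellular matrix genes (−0.016) ranked lower, with adjusted p = 0.531, adjusted p = 0.321, adjusted p = 0.531 and adjusted p = 0.531 with an estimated correlation. Without day 150 replicate 2 these 4 calls were lost, the myelin slope turned to 0.002, and the others were −0.005, −0.028 and −0.005. With 1 library left out they were kept in 15, 17, 14 and 10 of 20 runs, and in 5, 6, 3 and 3 of 9 other settings. The myelin call was also lost without day 0 replicate 1 (−0.019) or 3 (−0.017), day 120 replicate 3 (−0.011) or day 150 replicate 3 (−0.017), and its slope was −0.035 without day 120 replicate 1 and −0.027 without day 30 replicate 3 or day 150 replicate 1. That of the neuron and synapse genes was also lost without day 0 replicate 1 (−0.010) or day 120 replicate 3 (−0.009). The leukocyte call was also lost without day 0 replicate 1 (−0.048) or 2 (−0.042), day 120 replicate 2 (−0.041) or 3 (−0.033) or day 150 replicate 3 (−0.022). That of the extracellular matrix genes was also lost without any 1 library of day 0 or day 120, and without day 30 replicate 2 (−0.009) or 3 (−0.014) or day 150 replicate 3 (−0.018), and its slope was −0.025 without day 150 replicate 1.

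Across the 6 day comparisons and the trend, 18 of 33 lists were called by camera at least once, in 51 calls, of which 0 held with an estimated correlation. Counted on its own, fry gave 13 calls. The deiodinase genes dio2 and dio3, which set local thyroid hormone in seasonal animals, were at 1.78 ± 0.488 and 3.43 ± 0.970 FPKM at day 0 and gave F test adjusted p of 0.832 and 0.499. The list of thyroid hormone and photoperiod genes was among the 15 with no call in any comparison. The others were nonvisual opsins, retina genes, clock genes by symbol, cell proliferation, neural progenitors, cold-inducible RNA-binding genes, fatty acid synthesis, immediate early genes, astrocyte and radial glia, erythrocyte, endothelial, choroid and ependyma, skeletal muscle, and skin and cartilage markers. Camera adjusted p values of these lists were 0.0503 or above. Few members of some were tested: 4 genes for 23 opsin symbols, 8 for 37 retina, 10 for 37 clock and 4 for 12 cold-inducible symbols. It was 5 for 32 erythrocyte, 3 for 35 muscle, 3 for 30 skin and cartilage and 10 for 18 thyroid and photoperiod symbols. Camera asks for a shared direction, so members that move in opposite ways can cancel. The absence of a call therefore does not show that these genes were unchanged. Some lists with calls were thin too: 7 genes for 40 leukocyte symbols, 14 for 42 interferon and 4 for 14 pituitary hormone symbols. Their calls cover the tested members only. The neuropeptide genes gnrh1, gnrh3, kiss-1 and kiss-2 also did not pass, nor did growth hormone (LOC101171460), which ranged from 148 to 4892 FPKM between libraries.

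**Figure D4:**
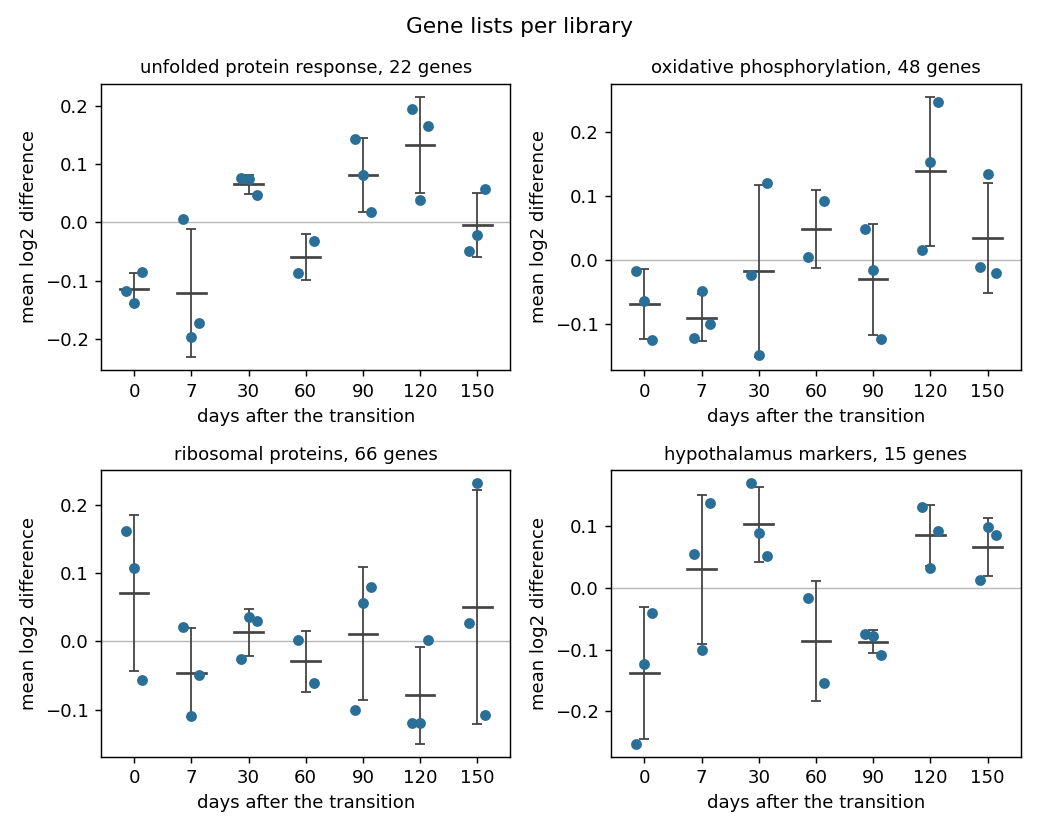
Mean log2 difference from each gene's mean over the 20 libraries, by day, for 4 gene lists; each point is a library, the horizontal line the mean and the bar 1 SD. For the unfolded protein response list the 3 libraries of day 120 lie above the 3 of day 0.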

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

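The settings that left out 2 libraries, and those applied to the lists other than the estimated correlation and fry, were chosen after seeing the data; the rest were set before. Counts of genes not given here stayed within 1.5 times their value. With a pseudocount of 0.1 day 30 gave 3 genes; without a filter the trend gave 0; with a mean of at least 5 FPKM day 90 gave 1. Quantile normalization and rescaling to the same total each gave 3 at day 120, and a prior without a trend 6 at day 7 and 3 at day 120. Sample weights gave 5 at day 30, 2 at day 90 and 8 at day 120. Spread from the compared groups only gave 2 at day 7, 2 at day 30, 4 at day 60 and 8 at day 120. The trend gave 0 over days 7 to 150 and 0 on log2(day + 1). Without day 60 replicate 1 and day 150 replicate 2 the counts were 25 over all days, 6 at day 7, 5 at day 30, 7 at day 60, 13 at day 120 and 0 for the trend. Without day 90 replicates 1 and 3 they were 6 at day 7, 5 at day 90 and 0 for the trend, and the interferon list at day 90 reversed to a median of −0.062. Leaving out 1 library at a time gave 7 to 37 genes over all days, 9 to 47 over days 7 to 150, 1 to 11 at day 7, 0 to 4 at day 30, 1 to 26 at day 60, 0 to 60 at day 90, 0 to 11 at day 120, 0 to 1 at day 150 and 0 to 7 for the trend. The 51 list calls became 0 with an estimated correlation and 13 in fry, and 39 to 59 with 1 library left out. The ribosomal list at day 7 reversed to a median of 0.017 after quantile normalization, and at day 90 its median was 0.002. Except where fewer samples or genes were tested, the cause was not tested. Named genes kept their direction in the runs of the gene tests that gave one. Median shifts of all genes stayed within 0.1 on the log2 scale. No paired analysis was possible because the labels give no replicate numbers shared between days. Depth is unknown, so counting error could not be separated from other spread.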

Other observations

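Tests of the splits of the samples were set before the results were seen, and the other tests here were chosen only after them. Clock genes were taken by protein description, since most carry a locus number and escape a list of symbols. At an unadjusted p under 0.05, 5 of those not called were higher at day 7 than at day 0: NFIL3 (LOC101175377) by 0.94 on the log2 scale, a second NR1D1 gene (LOC101173939) by 0.60, 2 ROR-beta genes (LOC101164545 and LOC101170052) by 0.46 and 0.33, and ARNTL1 (LOC101159313) by 0.35. Lower were 11: a PER2 gene (LOC101159817, −0.89), 2 NR1D2 genes (LOC101156434, −0.80, and LOC101163230, −0.45), per1 (−0.63), 2 cryptochrome genes (LOC101174986, −0.53, and LOC101160902, −0.49), 3 TEF genes (LOC101172818, −0.44, LOC101159928, −0.23, and LOC101164258, −0.18), an NFIL3-like gene (LOC101161892, −0.355) and bhlhe41 (−0.30). Other copies, such as nfil3 (0.18) and per2 (−0.22), were not among them. None of these genes passed over all genes tested.

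The 10 genes called at day 7 include 2 clock genes, NR1D1, kept in 19 of 20 runs with 1 library left out, and ARNTL2, kept in 4. Scaling of the deposited values is argued against, since the median size of the 10 changes was 0.756 as deposited and 0.754 after quantile normalization, where 8 still passed. Of 31 other clock genes, 16 had an unadjusted p under 0.05 at day 7, 5 higher and 11 lower, against a median of 3 and a highest count of 10 in 10000 random lists of the same level. The random lists were matched on level only. Clock genes may move together from library to library, which random genes need not do. The random counts therefore do not give the chance level for 3 samples against 3. The count was 4, 1, 8, 8 and 7 at days 30, 60, 90, 120 and 150 (random 95th percentiles 5, 5, 6, 6 and 6), all against the same 3 day 0 libraries, so the days were not set against each other. A hypothesis is that the day 7 or the day 0 samples may have been taken at another hour of the daily cycle, but a shift of the clock itself predicts the same counts, and the hour is not given, so both stay open.

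Gonadotropin subunits lhb and cga were higher at day 120 by 2.97 and 2.94. More pituitary tissue as a whole would raise the other pituitary genes alike, but 9 of them had a median change of 0.39 with an SD of 0.50. Among them were prolactin, somatolactin, pomc, thyrotropin beta, pitx1 and pou1f1. Their changes ran from 0.02 (thyrotropin beta) to 1.72 (growth hormone), with standard errors of up to 1.26. The largest error is that of prolactin, whose spread, shared by all days, includes 4.79 and 1910 FPKM in day 60 replicates 1 and 2. These values cover the pituitary as a whole, and a larger share of some part of it was not tested. After quantile normalization, lhb, npb and the peptide YY-like gene kept a median change of 2.89. A different share of females between days stays open and untested, because sex is not given, as does a biological change with time. A candidate explanation is a change in gonadotropes at day 120, found on the same data as the tests above and not itself tested.

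Day 60 replicate 1 was low in pituitary genes. For 6 pituitary transcription factors, picked afterwards from a list fixed beforehand, the median difference from the other libraries was −1.35 (SD 1.13) on the log2 scale, with pou1f1, pitx1 and lhx3 lowest, while the whole list of 13, which holds genes also expressed in brain, had a median of −0.03. The median of 15 hypothalamus markers was −0.007 (SD 0.215), and that of 9 telencephalon markers −0.08 (SD 0.66). The low values were thus not shared by these markers as a set. FPKM is scaled to each library's total, so a general loss of quality need not lower them, and their medians cannot decide against it. The library lay at −24.0 on the second principal component, the lowest of the 20, so a difference in quality stays open. Less pituitary tissue in that library may explain the pattern, found and tested on the same data, and a biological difference of this sample stays open and untested.

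Random splits bear on the counts. Over all days, 1 of 100 splits, the real one with 15 genes, gave as many, with 11 in the highest other. Over days 7 to 150 it was 1 of 100, with 14 in the highest other. Chance is thus unlikely for both counts, for the second by a margin of a single gene, but 100 splits do not exclude it. These 2 counts fell to 7 and 9 with 1 library left out, below the highest other split of the full set, and no splits were run for those runs. For the trend, 8 of 100 splits gave as many as the real 1 gene, with 6 in the highest, so chance cannot be excluded. For the lists, 1 of 100 splits, the real one, gave as many as the real 51 calls, with 50 in the highest other. Chance is thus unlikely, though not excluded, for the total of the full set only, by a margin of a single call. With 1 library left out the total ran from 39 to 59, at its lowest below that highest other split, and no splits were run for those runs. The median of the others was 27, so many single list calls with a preset correlation arise by chance. With 10 splits of 6 samples, no share under 0.05 can be reached: day 7 gave 10 genes against 0 in the highest other (1 split as large), and day 120 gave 5 against 1 (1 split). Days 30, 90 and 150 gave 0 genes, against 0, 0 and 1 in the highest other, so that 10 of 10 splits were as large.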
